A study of Mus musculus with 30 samples.

How the data were processed

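The authors deposited 1 table of TPM values for the 30 libraries, and these values were used as given. Their notes name bcl2fastq 2.20, Bowtie 0.12.2 and RSEM, which estimates transcript abundance from aligned reads, and the genome builds mm10 and GRCm38 without saying what each was used for. TPM holds no read counts, so a count model could not be used and the depth of a library is not known. The table has 41346 entries for 31427 gene symbols. The 6 single libraries were quantified against another transcript set than the 24 replicated ones: 9919 symbols stand in 2 entries, and 7571 of these hold values from both sets. Entries of a symbol were summed within each set, and levels were never compared between sets. All columns matched a sample, no pair of libraries held identical values, and replicates correlated across genes with Pearson r between 0.987 and 0.994 (genes are not independent replicates). The most abundant gene took 2.08% to 6.84% of a replicated library and 2.13% to 2.30% of a single one.

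For the replicated libraries, limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with a mean for each of the 12 groups and a trended prior variance, over 11842 genes with at least 1 TPM in at least 2 of the 24 libraries. This leaves 12 residual degrees of freedom, shared by all comparisons, and 11 with the replicate number as a block. Tests are two-sided. P-values were adjusted by Benjamini-Hochberg within each of 20 comparisons, and a gene was called at an adjusted p under 0.05. The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Mutant against WT under the same interferon used the same fit, for named genes and lists. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, TMM and quantile scaling, robust variances, the replicate block, the compared groups alone, a fold of at least 2, and leaving out 1 library at a time. Comparisons that share control libraries were set against each other only by direct contrasts. Nothing in the labels says that the 2 replicates of a group are separate cultures, so the p-values measure the spread between these samples and no more. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the single libraries, and matplotlib 3.10.9 for the plots.

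Each replicate number carries 1 date-like code in the sample titles, and the numbers were therefore taken to pair the samples. Deviations of same-numbered samples from their group means correlated above 0.1 in 56 of 66 pairs of groups (median 0.233, from −0.160 to 0.481), and the third principal component, with 11.0% of the variance, followed the number (r2 = 0.657). The fit with the number as a block is given beside a count that it moves by over 1.5 times and beside a named gene whose call it changes. Each code holds 1 library per group, so no comparison could be tested within 1 code.

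The rule for named genes takes, per comparison, the 5 called genes with the largest fold change in each direction, with a mean of at least 5 TPM in the higher group and both libraries of one group above both of the other. For interactions it asks for a call and a mean of at least 5 TPM in 1 of the 4 groups. It adds up to 4 called members of each list with the smallest p, and 18 genes fixed by name, among them Irf1, Irf2, Cd274, Tap1, Tap2, Psmb8 and Psmb9.

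The 19 gene lists are MHC class I presentation, MHC class II presentation, checkpoint and costimulatory ligands, ISGF3-type antiviral genes, interferon-inducible GTPases, GAS-type interferon gamma genes, interferon receptor and JAK-STAT signalling, the IRF family, nucleic acid and TLR sensing, cell death effectors, cytokines and chemokines, NF-kB feedback and LPS early genes, constitutive proteasome subunits, cell cycle, dendritic cell markers, macrophage and monocyte markers, lymphocyte markers, fibroblast and stromal markers, and stress and immediate early genes. They were tested with camera at a preset correlation of 0.01, adjusted over 380 tests, and over 114 more for mutant against WT under interferon. Of the 380 tests 147 were called, and 75 were also called with an estimated correlation. The test fry, which asks whether the genes of a list move one way on balance, was run alongside. Its result is printed for a few lists, and for some of them it differs from that with an estimated correlation, in both directions. In the single libraries, differences of log2(TPM + 1) have no test, and list medians were placed among 10000 random lists of the same size matched on expression.

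The method was tried on simulated values for IRF2KO against WT in media, with 200 genes changed by a known fold in each of 5 draws. Values were drawn independently for each gene around its mean over the 24 libraries, with its residual SD and no replicate effect. Changed genes had a mean log2(TPM + 1) of at least that of 5 TPM. In these draws the method recovered 33.6% of 1.5-fold, 67.2% of 2-fold, 95.2% of 4-fold and 99.2% of 8-fold changes, with 5.7% of calls false. A list with every member raised by 1 on the log2(TPM + 1) scale had an unadjusted camera p under 0.05 in 5 of 5 draws. So did 2 of 90 tests of unchanged lists. Because the simulated genes were independent, these draws do not show how the list test behaves for correlated genes.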

Results

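RNA sequencing measured transcript abundance in DC3.2 cells, a mouse dendritic cell line, in 30 libraries. Of these, 24 form 12 groups of 2 libraries, with 4 genotypes and 3 treatments. The genotypes are WT, IRF1KO, IRF2KO and DKO, the last with both interferon regulatory factors IRF1 and IRF2 targeted, and each was kept for 2 h in media, with IFNα at 5000 U/mL or with IFNγ at 2 ng/mL. The other 6 libraries have no replicate and hold WT and IRF2KO cells at 0 h, after 2 h with IFNα and after 2 h with LPS, whose dose the labels do not give. All are described as DC3.2, while the titles of the replicated libraries read DC32R and those of the single ones Dc3.2. IRF1KO, IRF2KO and DKO name the libraries with those labels. In the replicated titles WT reads nosg, IRF1KO reads IRF1sg and IRF2KO reads IRF2sg. No label names a control for the targeting, so effects of the targeting itself were not separated. All values are TPM, a normalised share of each library that keeps no read totals, so the depth is unknown. Between 10911 and 11101 genes reached 1 TPM in the replicated libraries, and between 9971 and 10186 in the single ones. The series asks which transcripts differ between these lines with and without interferon. Fold changes below are log2 values with their SE, and n = 2 libraries per group.

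In media, Irf1 (chromosome 11, 53770014 to 53778374 on GRCm38) had a mean of 21.1 ± 1.99 TPM (SD, n = 2) in WT, 27.1 ± 5.0 in IRF1KO and 32.1 ± 5.56 in DKO. Irf2 (chromosome 8, 46739745 to 46847458) had 24.3 ± 1.22 TPM in WT, 17.8 ± 0.59 in IRF2KO and 20.5 ± 0.59 in DKO. The difference of Irf2 between IRF2KO and WT was −0.43 ± 0.14 (adjusted p = 0.36, limma), and that of Irf1 between IRF1KO and WT was 0.34 ± 0.17. An edit that ends a protein need not lower its mRNA, so these values do not check the lines.

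The first question is what interferon does in WT cells. After 2 h of IFNα, antiviral genes rose. Rtp4 rose by 5.99 ± 0.25, from 0.17 TPM in media to 73.6 TPM. Ifit1, whose product binds viral RNA, rose by 4.55 ± 0.22, Usp18, a protease that removes ISG15 from proteins and restrains the interferon receptor, by 4.54 ± 0.22, and Irf7, a transcription factor of type I interferon genes, by 4.36 ± 0.21. Of the ISGF3-type antiviral genes, 31 of 41 tested members rose and 0 fell (38 rose adjusted over the list alone). Of the interferon-inducible GTPases, which act on vacuoles that hold pathogens, 13 of 17 rose (16 adjusted over the list alone), with Irgm1 at 3.93 ± 0.13 and Igtp at 3.90 ± 0.20. Irf9 rose by 2.86 ± 0.14 and Stat2 by 2.61 ± 0.26, among 5 of 19 members of the interferon receptor and JAK-STAT list (5 adjusted over the list alone). In the IRF family 3 of 11 rose (5 adjusted over the list alone), among them Irf1 by 3.03 ± 0.17. Of the nucleic acid and TLR sensing genes 6 of 28 rose (8 adjusted over the list alone), with the RNA sensors Ddx58 at 2.65 ± 0.19 and Ifih1 at 1.22 ± 0.15. The peptide transporter gene Tap1 rose by 1.85 ± 0.17, as 1 of 22 genes of MHC class I presentation (2 adjusted over the list alone, 2 with the replicate number as a block). Cd274, which encodes the checkpoint ligand PD-L1, had 0.99 ± 0.24 (adjusted p = 0.072) and was called with the replicate number as a block, at the same 0.99. Of the GAS-type interferon gamma genes 5 of 21 rose (10 adjusted over the list alone, and 8 over all genes with the replicate number as a block), among them the chemokine gene Cxcl10 by 4.12 ± 0.58.

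In this comparison limma called 123 genes higher and 0 lower of 11842 (163 and 4 with the replicate number as a block), with 557 at an unadjusted p under 0.05 in either direction. Every called gene moved the same way in both replicate numbers, here and in the comparisons that follow. The list test camera called these 7 lists higher, and the calls hold with an estimated correlation (ISGF3-type genes adjusted p = 2.3e-06, GTPases 7.8e-05, sensing 0.027). Cytokines and chemokines (2 of 22 rose, and 5 with the block), NF-kB feedback genes (1 of 20) and cell death effectors (0 of 21, and 2 with the block) were called as well, with adjusted p = 0.21, 0.65 and 0.10 with an estimated correlation.

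After 2 h of IFNγ, GTPase genes rose in WT cells. Of the 17 tested, 16 rose (17 adjusted over the list alone). Gbp2 (chromosome 3, 142620663 to 142638008), a guanylate-binding protein gene, rose by 6.71 ± 0.41, from 2.70 ± 2.52 TPM (SD, n = 2) to 339 ± 7.34 TPM. Tgtp1 rose by 6.42 ± 0.22, Iigp1 by 5.84 ± 0.25 and Igtp by 5.72 ± 0.20. Reads of near-identical GTPase genes, such as Tgtp1 and Tgtp2, are hard to assign, so values of single members carry that uncertainty. Of the GAS-type genes 12 of 21 rose and 1 fell (17 and 1 adjusted over the list alone), with Cxcl10 at 5.02 ± 0.58 and the adhesion gene Icam1 at 1.78 ± 0.13. Irf1 rose by 4.40 ± 0.17 to 470 ± 88.3 TPM, and Irf8, a factor of dendritic cell development, by 2.67 ± 0.14. MHC class I presentation had 3 of 22 members up (6 adjusted over the list alone), among them Tap1 at 2.64 ± 0.17 and the immunoproteasome gene Psmb9 at 1.31 ± 0.22. Cd274 rose by 1.64 ± 0.24 to 95.7 ± 22.4 TPM, as 1 of 2 members up among 12 checkpoint and costimulatory ligands (3 adjusted over the list alone; adjusted p = 0.080 with an estimated correlation). The list member that fell was Cish, a feedback inhibitor of cytokine signalling, at −1.17 ± 0.26, a call lost without WT IFNγ replicate 2, WT media replicate 1 or WT media replicate 2 (−1.59 to −0.74), and without the filter on low values.

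In the same comparison limma called 142 genes higher and 7 lower, against 206 and 23 with the replicate number as a block. The total of 149 fell to 93 without WT media replicate 2. The ISGF3-type genes had 11 of 41 members up (25 adjusted over the list alone), the JAK-STAT list 5 of 19 and the IRF family 3 of 11. Calls by camera of these lists, the GTPases, the GAS-type genes and MHC class I presentation hold with an estimated correlation (adjusted p = 8.5e-06 for the GTPases and 0.00053 for the ISGF3-type genes). Sensing genes (4 of 28), NF-kB feedback genes (2 of 20, and 4 with the block), cell death effectors (2 of 21), dendritic cell markers (1 of 11, and 2 with the block) and cytokines and chemokines (2 of 22, and 5 with the block) were called with adjusted p = 0.18, 0.19, 0.19, 0.069 and 0.56 with an estimated correlation.

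The 2 interferons were then set against each other in WT cells. The neuronal tubulin gene Tubb3 was higher with IFNγ by 4.19 ± 0.27, Tgtp1 by 3.34 ± 0.22, Gbp2 by 3.27 ± 0.41, Irf8 by 2.19 ± 0.14 and Irf1 by 1.37 ± 0.17. Rtp4 (−4.86 ± 0.25), Irf7 (−3.59 ± 0.21), Ifit3 (−3.45 ± 0.24) and Usp18 (−3.43 ± 0.22) were lower with IFNγ. Of the ISGF3-type genes 23 of 41 were lower and 0 higher with IFNγ (29 adjusted over the list alone), while 15 of 17 GTPases were higher (16 adjusted over the list alone). Of the GAS-type genes 4 of 21 were higher (12, and 1 lower, adjusted over the list alone; 11, and 1 lower, with the block). The 3 lists were called with an estimated correlation too (adjusted p = 8.2e-06, 0.00019 and 0.0020). Sensing genes (1 higher and 2 lower of 28) were called lower, and NF-kB feedback genes (1 of 20 higher, 2 with the block) and dendritic cell markers (1 of 11 higher, and 2 with 1 lower with the block) higher, with adjusted p = 0.29, 0.51 and 0.062 with an estimated correlation. In total 49 genes were higher and 42 lower, against 105 and 72 with the replicate number as a block.

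**Figure D1:**
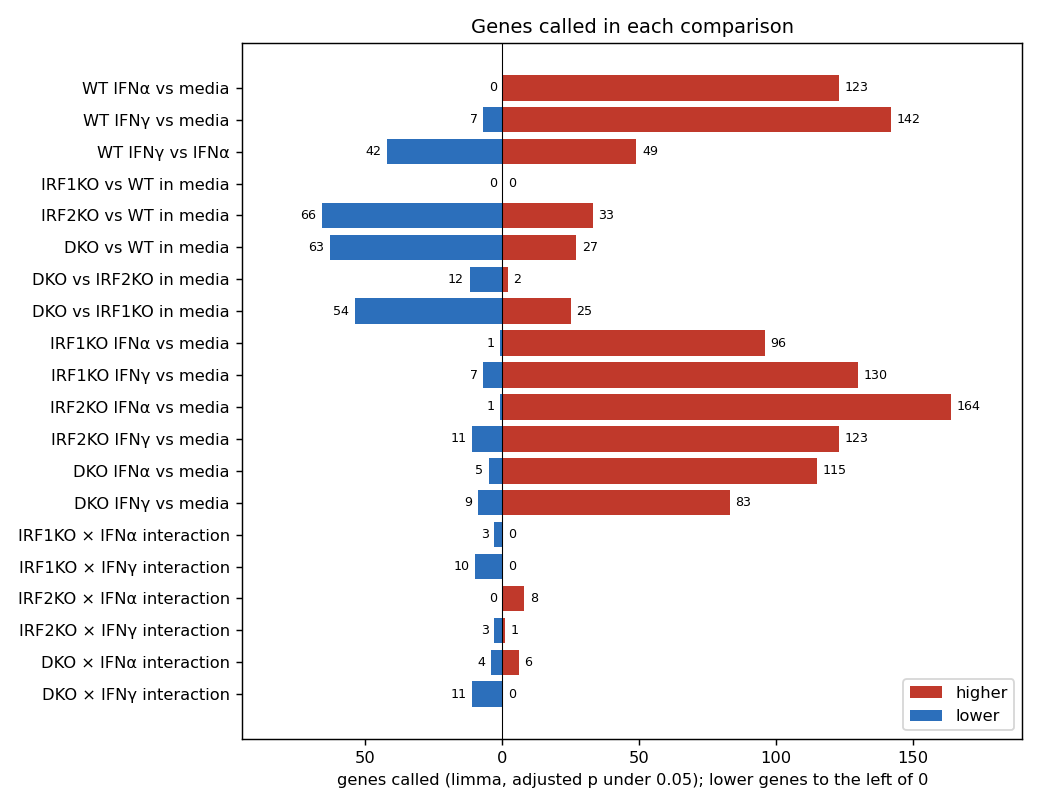
Bars give the number of genes called by limma in each comparison, higher to the right of 0 and lower to the left. The IFNα response of WT has 123 higher and 0 lower genes, and IRF1KO against WT in media has 0 of either.

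In media, the comparison of IRF2KO with WT asks what differs in the IRF2KO line without added interferon. Guanylate-binding protein genes were higher in IRF2KO. Gbp2 was higher by 6.14 ± 0.41, at 239 ± 105 TPM (SD, n = 2) against 2.70 ± 2.52 in WT. Gbp3 was higher by 5.16 ± 0.25, at 223 ± 3.92 against 5.26 ± 0.11 TPM, Gbp4 by 4.39 ± 0.28, Gbp5 by 3.42 ± 0.22 and Gbp7 by 3.31 ± 0.16. Gbp2, Gbp3, Gbp5 and Gbp7 lie on chromosome 3 between 142496934 and 142638008, and Gbp4 lies on chromosome 5 from 105115767 to 105139586. In the GTPase list 11 of 17 rose and 0 fell (13 adjusted over the list alone; adjusted p = 0.00075 with an estimated correlation). Gsdmd (chromosome 15, 75862144 to 75867408), which encodes the pore-forming gasdermin D, was at 3.18 ± 0.88 TPM against 31.1 ± 3.63 (−2.95 ± 0.24). The sensor genes Ifih1 (−2.05 ± 0.15) and Ddx58 (−1.41 ± 0.19) fell, as did Tlr3 (−0.93 ± 0.19), the receptor for double-stranded RNA. They are the 3 of 28 sensing genes that were called, with 0 higher, and camera did not call that list (adjusted p = 0.12). The cathepsin gene Ctso (−3.12 ± 0.17) and Acadl (−3.18 ± 0.26), an enzyme of fatty acid oxidation, were lower too.

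MHC class I presentation moved both ways in IRF2KO in media, with 1 of 22 members higher and 3 lower (1 and 6 adjusted over the list alone, 1 and 5 with the replicate number as a block), and camera did not call it (adjusted p = 0.33). Tap2 (chromosome 17, 34204479 to 34216321), a subunit of the peptide transporter, fell (−2.25 ± 0.29), from 40.7 ± 4.47 to 8.36 ± 4.62 TPM (SD, n = 2). Erap1 (chromosome 13, 74639573 to 74693205), which trims peptides, fell (−1.41 ± 0.23), and the immunoproteasome gene Psmb8 (chromosome 17, 34198195 to 34201454) rose by 0.88 ± 0.12. Psmb9 (chromosome 17, 34182030 to 34187330) had −0.96 ± 0.22 (adjusted p = 0.069) and was called with the block, at the same −0.96. ISGF3-type genes also moved both ways, with 1 member higher and 5 lower of 41 (5 and 8 adjusted over the list alone), among them Epsti1 at −1.96 ± 0.23 and Parp14 at −1.67 ± 0.20. For that list the adjusted p was 0.090 by camera, 0.67 with an estimated correlation and 0.037 by fry. The member that rose was Cmpk2 at 1.23 ± 0.24, named after its value was seen. Dendritic cell markers (1 of 11 fell, and 3 with the block) and cell cycle genes (0 of 25, and 1 with the block) were called lower and GAS-type genes (0 of 21, and 3 with the block) higher by camera, with adjusted p = 0.062, 0.65 and 0.41 with an estimated correlation. By fry the lists just named had adjusted p = 0.0035, 0.39 and 0.68 in the same order. In total limma called 33 genes higher and 66 lower, against 74 and 139 with the block. Without IRF2KO media replicate 1 or 2 the total was 45 or 57, and without WT media replicate 1 or 2 it was 47 or 40. The call of Erap1 was lost without IRF2KO media replicate 2 or WT media replicate 2 (−1.53 to −1.30), that of Cmpk2 in 3 of 4 such fits (0.97 to 1.49) and that of Tlr3 in all 4 (−1.0 to −0.86). At a pseudocount of 5 neither Cmpk2 (0.36) nor Tlr3 (−0.42) was called.

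In DKO cells in media, MHC class I presentation was lower than in WT. Of 22 members 10 fell and 0 rose (11 adjusted over the list alone; adjusted p = 0.00012 with an estimated correlation). Tap2 fell to 2.38 ± 0.50 TPM (SD, n = 2; −3.63 ± 0.29), Erap1 to 3.78 ± 0.18 TPM (−3.50 ± 0.23) and Psmb9 (−3.05 ± 0.22) from 32.0 ± 0.14 to 2.98 ± 0.10 TPM. The proteasome activator gene Psme1 (−1.88 ± 0.20), Psmb8 (−1.07 ± 0.12) and the class I heavy chain gene H2-K1 (−0.75 ± 0.10) fell as well. Gbp2 was higher by 5.51 ± 0.41, Gbp3 by 5.04 ± 0.25 and Gbp7 by 3.42 ± 0.16, among 7 of 17 GTPases that rose (7, and 1 that fell, adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). Of the ISGF3-type genes 7 of 41 fell and 0 rose (15 fell and 1 rose adjusted over the list alone, 11 and 1 with the block; adjusted p = 0.0077 with an estimated correlation), with Ifih1 at −2.13 ± 0.15 and Parp14 at −2.05 ± 0.20. Gsdmd (−3.09 ± 0.24), Ctso (−3.22 ± 0.17), Nmi (−3.08 ± 0.20) and Tlr3 (−1.78 ± 0.19) fell. Checkpoint ligands (0 of 12, and 4 up with the block) were called higher, and dendritic cell markers (2 of 11 fell), sensing genes (3 of 28 fell; not called with the block) and cell cycle genes (0 of 25) lower, with adjusted p = 0.068, 0.052, 0.62 and 0.65 with an estimated correlation. By fry the lists just named had adjusted p = 0.0075, 0.048, 0.26 and 0.86 in the same order, and the GTPases 6.5e-05. limma called 27 genes higher and 63 lower, against 85 and 105 with the replicate number as a block. The total of 90 was 54 or 47 without DKO media replicate 1 or 2, and 42 or 53 without WT media replicate 1 or 2.

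Against IRF2KO, which differs from DKO in the IRF1 label, class I presentation was again lower in DKO. Psmb9 (−2.09 ± 0.22), Erap1 (−2.08 ± 0.23) and Psmb8 (−1.94 ± 0.12) were lower, the 3 members of 22 that passed (12 adjusted over the list alone, 7 with the block; adjusted p = 7.4e-05 with an estimated correlation). Psmb8 stood at 339 ± 33.7 TPM (SD, n = 2) in IRF2KO, 184 ± 4.42 in WT and 87.4 ± 8.85 in DKO. The interferon-responsive nuclear body gene Sp110 (−1.43 ± 0.16) and Irgm1 (−1.31 ± 0.13) were lower, the latter 1 of 3 GTPases that fell (7 adjusted over the list alone, 5 with the block; adjusted p = 0.015 with an estimated correlation). Of the ISGF3-type genes 1 of 41 fell (4 adjusted over the list alone), with a list median of −0.108. For that list the adjusted p was 0.018 with an estimated correlation and 0.10 by fry. In total 2 genes were higher and 12 lower, against 3 and 20 with the replicate number as a block, and the total of 14 was 22 at a pseudocount of 0.1, 8 at 5, 8 without DKO media replicate 2 and 7 without IRF2KO media replicate 1. The median of all genes here was 0.134 and under TMM scaling 0.014, and the named genes fell under both.

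Against IRF1KO, which differs from DKO in the IRF2 label, the Gbp genes were higher in DKO, Gbp2 by 6.56 ± 0.41, Gbp3 by 5.37 ± 0.25 and Gbp7 by 3.74 ± 0.16. Tap2 (−3.43 ± 0.29), Erap1 (−3.32 ± 0.23), Gsdmd (−3.14 ± 0.24) and Psmb9 (−2.29 ± 0.22) were lower. Class I presentation had 7 of 22 members lower (10 lower and 1 higher both adjusted over the list alone and with the block), the GTPases 7 of 17 higher (7, and 1 lower, adjusted over the list alone) and the ISGF3-type genes 6 of 41 lower (11, and 1 higher, adjusted over the list alone). Their calls hold with an estimated correlation (adjusted p = 0.0011, 0.029 and 0.023), as do those of checkpoint ligands, higher (0 of 12, and 5 with the block; 0.048), and dendritic cell markers, lower (2 of 11; 0.025). limma called 25 genes higher and 54 lower, against 107 and 94 with the replicate number as a block. The total of 79 was 46 or 38 without DKO media replicate 1 or 2, and 52 or 49 without IRF1KO media replicate 1 or 2.

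**Figure D2:**
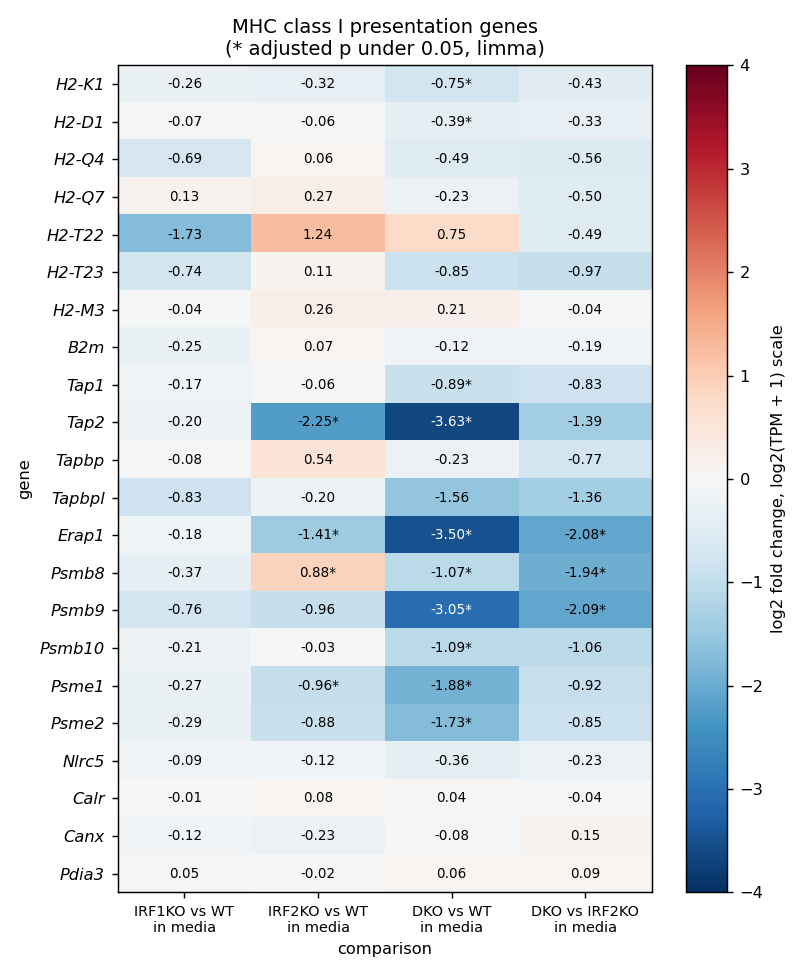
Cells give the log2 fold change of each tested MHC class I presentation gene (vertical axis) in 4 comparisons in media (horizontal axis), n = 2 libraries per group, with a star where limma called it. In DKO against WT 10 genes fell, among them Tap2 at −3.63, and in IRF1KO against WT no gene has a star.

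Between IRF1KO and WT in media no gene passed the test. limma called 0 of 11842, with 305 at an unadjusted p under 0.05, and 0 with the replicate number as a block. The 305 are a share under 0.05 of the genes, fewer than would pass where nothing differs. They are no sign of missed differences and do not exclude them either, since too little power stays open. Psmb9 had −0.76 ± 0.22, Psmb8 −0.37 ± 0.12 and H2-K1 −0.26 ± 0.10 (adjusted p = 1 each). As a list, MHC class I presentation was lower, with a median of −0.207 over 22 genes and 0 members called (0 adjusted over the list alone; camera adjusted p = 1.1e-08, and 0.0083 with an estimated correlation). The GTPases and the ISGF3-type genes were called lower by camera, with adjusted p = 0.54 and 0.59 with an estimated correlation. Without IRF1KO media replicate 1 the count was 2, and without the filter on low values 3.

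In the mutant lines, antiviral genes and GTPases rose with IFNα. In IRF1KO, Rtp4 rose by 5.28 ± 0.25, Usp18 by 4.55 ± 0.22 and Irf7 by 4.34 ± 0.21, and 30 of 41 ISGF3-type genes rose (37 adjusted over the list alone), with 8 of 17 GTPases (13 adjusted over the list alone). In IRF2KO, Ifit1 rose by 7.08 ± 0.22, Cmpk2 by 6.58 ± 0.24, Ifit3 by 6.47 ± 0.24 and the ubiquitin-like modifier gene Isg15 by 5.94 ± 0.38. There 38 of 41 ISGF3-type genes rose (39 adjusted over the list alone), 12 of 17 GTPases (16 adjusted over the list alone) and 4 of 22 class I genes (12 adjusted over the list alone, 7 with the block), with Tap1 at 2.13 ± 0.17. In DKO, Ifit1 rose by 6.19 ± 0.22 and Usp18 by 5.36 ± 0.22, with 33 of 41 ISGF3-type genes (37 adjusted over the list alone) and 10 of 17 GTPases up (15 adjusted over the list alone). All these list calls hold with an estimated correlation (adjusted p between 2.3e-06 for the ISGF3-type genes in DKO and 0.010 for class I presentation in IRF2KO). Class I presentation was also called higher in IRF1KO (1 of 22 rose, adjusted p = 0.022 with an estimated correlation) and DKO (2 of 22, 0.0080). So were the JAK-STAT list (5 of 19 in each line, 0.013 and 0.0070) and the IRF family (3 of 11 in each line, 0.0076 and 0.0073). limma called 96 genes higher and 1 lower in IRF1KO, 164 and 1 in IRF2KO, and 115 and 5 in DKO, against 130 and 2, 213 and 2, and 150 and 29 with the replicate number as a block. The gene that fell was Hey1 in IRF1KO (−1.11 ± 0.22) and Wdr31 in IRF2KO (−0.94 ± 0.21), named after their values were seen. Hey1 lost its call in 3 of 4 fits without 1 library (−1.37 to −0.84) and Wdr31 in 2 of 4 (−1.30 to −0.59), the first also at a pseudocount of 0.1 (−1.69) and the second at 5 (−0.28). The total of 165 in IRF2KO was 108 without IRF2KO IFNα replicate 1.

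With IFNγ, GTPases and GAS-type genes rose in each mutant line. In IRF1KO, the surface antigen gene Ly6a rose by 4.94 ± 0.34, Irf1 by 4.60 ± 0.17 and Irgm1 by 4.58 ± 0.13, and 15 of 17 GTPases (16 adjusted over the list alone), 9 of 21 GAS-type genes (14, and 1 that fell, adjusted over the list alone) and 4 of 41 ISGF3-type genes rose. In IRF2KO, Cxcl10 rose by 5.71 ± 0.58, Igtp by 4.85 ± 0.20, Irgm1 by 4.76 ± 0.13 and Cd274 by 1.57 ± 0.24, with 14 GTPases (17 adjusted over the list alone), 11 GAS-type genes, 13 ISGF3-type genes and 4 class I genes up (7 of the last with the block). In DKO, Irgm1 rose by 5.40 ± 0.13, Cxcl10 by 5.39 ± 0.58, Igtp by 5.01 ± 0.20 and Psmb9 by 2.08 ± 0.22, with 10 GTPases (15 adjusted over the list alone), 8 GAS-type genes and 3 ISGF3-type genes up (6 of the last with the block). These lists were called with an estimated correlation too (adjusted p between 7.9e-05 for the GTPases in IRF1KO and 0.021 for the ISGF3-type genes in IRF1KO). Class I presentation was called higher in IRF1KO as well (3 of 22 rose, adjusted p = 0.046 with an estimated correlation). limma called 130 genes higher and 7 lower in IRF1KO, 123 and 11 in IRF2KO, and 83 and 9 in DKO. With the replicate number as a block these were 186 and 23, 215 and 28, and 153 and 43. The total of 137 in IRF1KO was 73 or 69 without IRF1KO IFNγ replicate 1 or 2 and 64 without IRF1KO media replicate 2. The total of 134 in IRF2KO was 67 without IRF2KO IFNγ replicate 1 and 83 without IRF2KO media replicate 1, and that of 92 in DKO was 51 or 54 without DKO media replicate 1 or 2.

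Whether a response differed between lines was tested as an interaction, the mutant's log2 response minus that of WT. The IRF1KO line had smaller responses of GTPase genes. To IFNα the response of Ifi47 (chromosome 11, 49076587 to 49096987) was smaller (−2.04 ± 0.24), with 9.96 ± 0.89 TPM (SD, n = 2) after treatment against 38.3 ± 0.83 in WT, and that of Gm12250 was smaller too (−3.55 ± 0.30). To IFNγ those of Gm12250 (−3.38 ± 0.30), Ifi47 (−2.61 ± 0.24) and Iigp1 (−2.94 ± 0.35; chromosome 18, 60373616 to 60392634) were smaller. Iigp1 reached 8.56 ± 2.19 TPM in IRF1KO and 78.7 ± 0.89 in WT. At a pseudocount of 0.1 the IFNγ differences of Gm12250 (−4.10) and Iigp1 (−2.76) were not called. Of 17 GTPases, 2 responded less to IFNα and 7 to IFNγ (13 each adjusted over the list alone; adjusted p = 0.00098 and 0.00012 with an estimated correlation). The ISGF3-type genes were called lower by camera in both (0 of 41 members, and 9 and 0 adjusted over the list alone; adjusted p = 0.062 and 0.016 with an estimated correlation). limma called 0 higher and 3 lower for IFNα (203 at an unadjusted p under 0.05), and 0 and 10 for IFNγ (175). The count for IFNα was 5 at a pseudocount of 5. The count for IFNγ was 2 at a pseudocount of 0.1, 4 without IRF1KO IFNγ replicate 1, 4 or 5 without WT IFNγ replicate 1 or 2, 4 without IRF1KO media replicate 2, and 6 or 4 without WT media replicate 1 or 2.

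In the IRF2KO line 8 genes had larger IFNα responses. Rsad2 (chromosome 12, 26442743 to 26456452), which encodes the antiviral enzyme viperin, reached 118 ± 31.2 TPM (SD, n = 2) in IRF2KO and 2.24 ± 0.16 in WT, from 0.87 ± 0.34 in IRF2KO media and a WT media group listed at 0. The response was larger by 2.73 ± 0.33 for its neighbour Cmpk2 (chromosome 12, 26469117 to 26479837), by 2.53 ± 0.32 for Ifit1, at 210 ± 84.2 against 24.6 ± 1.24 TPM, and by 2.62 ± 0.26 for Gm14446. Of the ISGF3-type genes 5 of 41 had a larger response (11 adjusted over the list alone). For that list the adjusted p was 0.059 with an estimated correlation and 0.0021 by fry. The GTPases were called lower by camera (0 of 17 members, and 2 higher and 2 lower adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). limma called 8 genes higher and 0 lower (394 at an unadjusted p under 0.05), and at a pseudocount of 0.1 in place of 1 none of the 8 was called. There Cmpk2 had 0.77 ± 0.77, Ifit1 1.37 ± 0.65 and Gm14446 2.24 ± 0.69. The count of 8 was 15 at a pseudocount of 5, 5 without IRF2KO IFNα replicate 1, 4 without WT IFNα replicate 1, and 5 without WT media replicate 1 or 2. The median of all genes was 0.142 in this test and 0.023 under TMM scaling. To IFNγ, Rsad2 was again higher, at 9.64 ± 2.84 TPM in IRF2KO, and Gbp2, whose media level was raised in IRF2KO, rose less (−4.64 ± 0.57), to 966 ± 188 TPM. Among GTPases 3 of 17 rose less (11, and 1 that rose more, adjusted over the list alone; adjusted p = 0.0035 with an estimated correlation). In total 1 gene was higher and 3 lower, against 2 and 5 with the replicate number as a block, and the total of 4 was 2 without IRF2KO IFNγ replicate 2 and 7 at a pseudocount of 5.

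In DKO both kinds of difference were present. To IFNα the responses of Gm12250 (−3.24 ± 0.30) and of the oligoadenylate synthetase-like gene Oasl2 (−1.82 ± 0.23) were smaller, while Rsad2 reached 22.7 ± 0.93 TPM (SD, n = 2). At a pseudocount of 0.1 Gm12250 (−3.37) and Oasl2 (−0.80) were not called. To IFNγ the responses of Gbp2 (−5.38 ± 0.57), Iigp1 (−4.11 ± 0.35), Gbp3 (−2.88 ± 0.35) and Ifi47 (−2.74 ± 0.24) were smaller. Gbp2 and Gbp3 started from raised media levels in DKO, 157 ± 79.5 and 205 ± 11.3 TPM, and reached 372 ± 11.2 and 266 ± 42.0 TPM, against 339 ± 7.34 and 58.8 ± 8.51 in WT. Iigp1 and Ifi47 reached 3.80 ± 2.28 and 12.5 ± 2.29 TPM, against 78.7 ± 0.89 and 71.0 ± 2.33 in WT. Of 17 GTPases, 2 responded less to IFNα (9, and 2 that responded more, adjusted over the list alone) and 8 to IFNγ (14 adjusted over the list alone, 10 with the block), with adjusted p = 0.014 and 0.00023 with an estimated correlation. The ISGF3-type genes had 2 members with a larger and 1 with a smaller response to IFNα (8 and 4 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation). limma called 6 higher and 4 lower for IFNα, and 0 higher and 11 lower for IFNγ (248 at an unadjusted p under 0.05; 0 and 17 with the replicate number as a block). At a pseudocount of 0.1 the totals of 10 and 11 were 1 and 7, and at 5 that for IFNα was 16. The total of 10 for IFNα was 3 without DKO IFNα replicate 1, 4 or 3 without DKO media replicate 1 or 2, 3 or 4 without WT IFNα replicate 1 or 2, and 4 or 3 without WT media replicate 1 or 2. In the 6 interaction tests camera called further lists not given here, and of these only the lymphocyte markers in DKO with IFNγ, given below, held with an estimated correlation (lowest adjusted p of the others = 0.076).

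**Figure D3:**
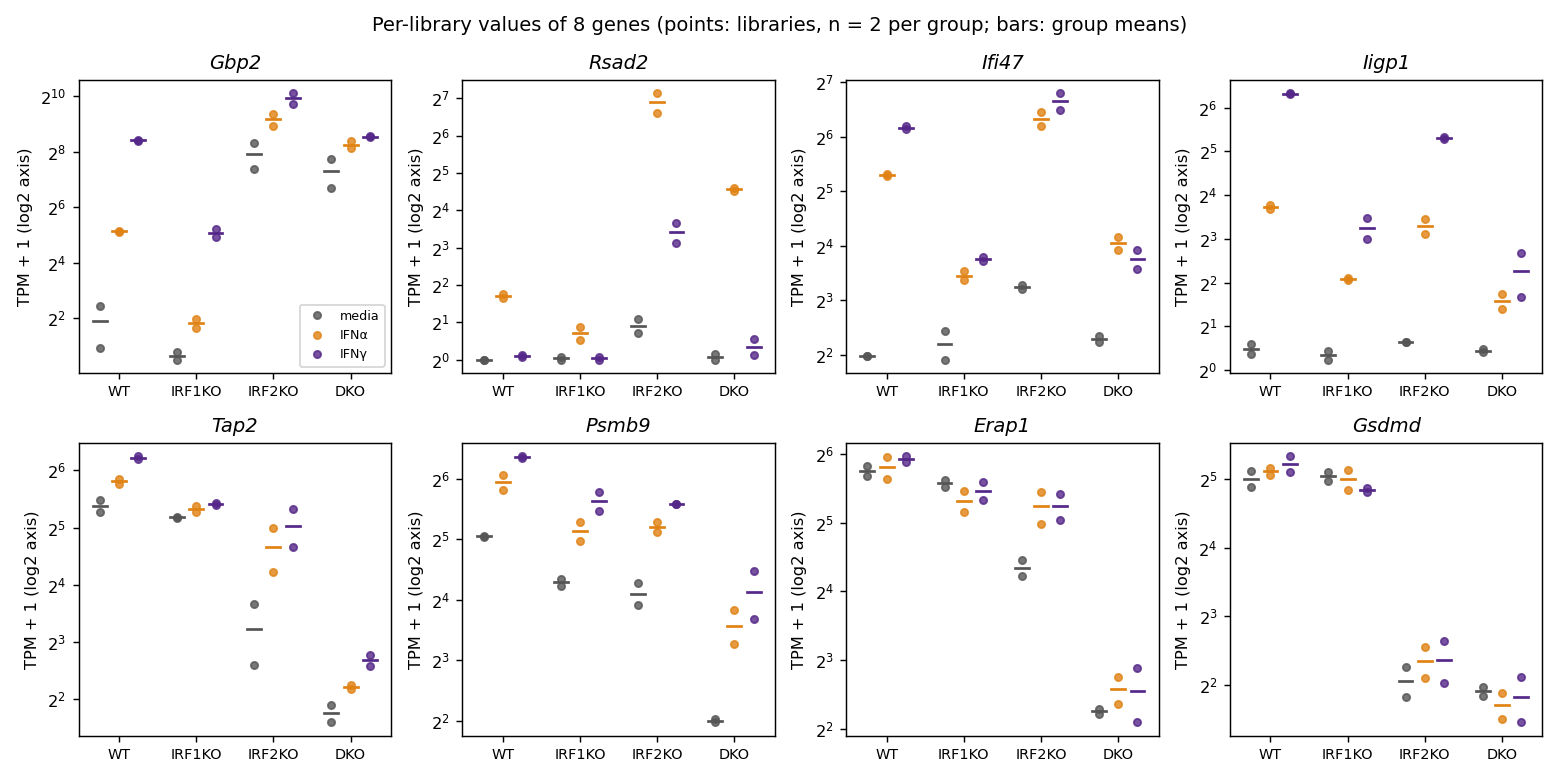
Points give TPM + 1 on a log2 axis for each of the 2 libraries of every genotype and treatment, and bars the group means, for 8 genes. Gbp2 in media lies at 239 TPM in IRF2KO and 2.70 TPM in WT, and Rsad2 with IFNα at 118 TPM in IRF2KO and 2.24 TPM in WT.

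Set against WT under the same interferon, IRF1KO cells had lower GTPase levels. With IFNα Gbp2 (−3.33 ± 0.41), Gbp4 (−2.38 ± 0.28) and Ifi47 (−1.84 ± 0.17) were lower, among 11 of 17 GTPases that were lower (15 adjusted over the list alone). With IFNγ Gbp2 was at 32.6 ± 4.51 TPM (SD, n = 2) against 339 ± 7.34, and 13 of 17 were lower (16 adjusted over the list alone). ISGF3-type genes were lower, 5 of 41 with IFNα and 2 of 41 with IFNγ (12 and 16 adjusted over the list alone; 5 and 4 with the block), and class I presentation with 0 of 22 members called under each (0 and 7 adjusted over the list alone; 0 and 2 with the block). These 3 lists were called with an estimated correlation under both interferons (adjusted p between 8.7e-05 and 0.0052).

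IRF2KO cells under interferon had Gsdmd at −2.78 ± 0.24 with IFNα and −2.89 ± 0.24 with IFNγ, Ifih1 at −2.27 ± 0.15 and −2.41 ± 0.15, and Tlr3 at −1.62 ± 0.19 and −1.80 ± 0.19, all lower than in WT. Gbp5 was higher by 4.52 ± 0.22 and 3.02 ± 0.22, and 12 and 5 of 17 GTPases were higher (13 and 10 adjusted over the list alone, with 1 lower under IFNγ; 12 and 7 with the replicate number as a block, with 1 lower under IFNγ; adjusted p = 0.0032 and 0.037 with an estimated correlation). ISGF3-type genes moved both ways, 9 higher and 4 lower of 41 with IFNα and 5 and 7 with IFNγ. For that list the adjusted p was 0.74 and 0.77 with an estimated correlation, and 0.016 and 0.32 by fry. DKO cells had lower class I genes than WT under interferon as well. With IFNγ Tap2 (−3.54 ± 0.29), Erap1 (−3.44 ± 0.23) and Psmb9 (−2.28 ± 0.22) were lower than in WT, and 9 of 22 members were lower with IFNα and 10 with IFNγ (12 and 11 adjusted over the list alone, with 1 higher under IFNα; adjusted p = 0.00046 and 0.00086 with an estimated correlation). Of the ISGF3-type genes 16 of 41 were lower in DKO with IFNγ (23 adjusted over the list alone; adjusted p = 0.0023 with an estimated correlation), with Parp14 at −3.49 ± 0.20. GTPases moved both ways in DKO with IFNγ, with 3 higher and 7 lower of 17 (adjusted p = 0.42 with an estimated correlation). With IFNα both lists moved both ways in DKO against WT. The ISGF3-type genes had 4 higher and 10 lower of 41, and the GTPases 6 higher and 4 lower of 17. Neither was called there with an estimated correlation (adjusted p = 0.42 and 0.77).

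The single libraries, n = 1 each and given without a test, hold WT and IRF2KO at 0 h. Over 10410 genes, 69 were at least 2-fold higher and 58 at least 2-fold lower in IRF2KO. Gbp2 was at 144 TPM in IRF2KO and 0.58 in WT, Gbp3 at 224 and 6.45, Gbp4 at 46.1 and 1.05, and Gbp5 at 14.4 in IRF2KO while it is listed at 0 in WT. Gsdmd was at 5.03 and 26.9 TPM, Tap2 at 10.2 and 28.1, Erap1 at 17.3 and 47.2, and Psmb8 at 279 and 149. Of the 99 genes called between IRF2KO and WT in media, 87 were quantified in the single libraries and 79 of these differed in the same direction (90.8%), 30 of 32 higher and 49 of 55 lower. Their median difference, taken in the direction of the call, was 0.696 on the log2 scale, against −0.074 to 0.037 for the central 95% of 10000 random lists matched on expression. With the replicate number as a block the calls number 213, and 170 of 196 quantified went the same way (86.7%). The 2 sets of libraries were quantified against different transcript sets, so their levels were not compared with each other.

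**Figure D4:**
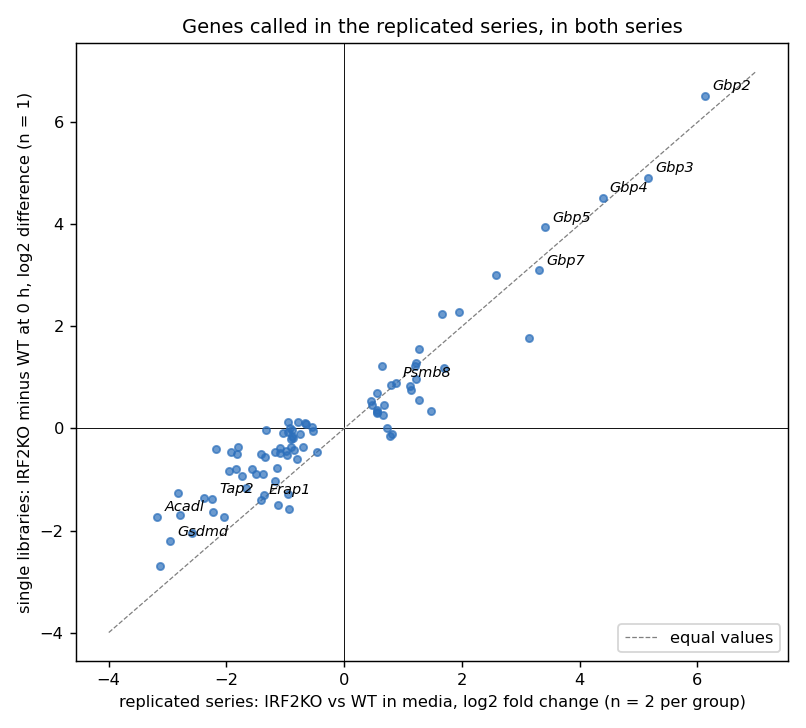
Each point is 1 of the 87 genes called between IRF2KO and WT in media that the single libraries also hold, with the log2 fold change of the replicated libraries (horizontal) and the log2 difference of the single libraries (vertical). Of these, 79 have the same sign in both.

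The other fixed lists gave little over the 20 comparisons with a count. MHC class II presentation (12 genes tested) and constitutive proteasome subunits (25) were called by camera in none, and fibroblast and stromal markers (2 of 14 listed were tested) in none either. Stress and immediate early genes were called in 6 and macrophage and monocyte markers in 3, and none of these calls held with an estimated correlation (lowest adjusted p = 0.29 and 0.57). The lymphocyte markers, of which 3 of 20 listed were tested, were called higher in 4, and 2 held, the IFNγ response of DKO (adjusted p = 0.022 with an estimated correlation) and its difference from WT (0.0070), with 1 member up in the first. Dendritic cell markers held in 3 of 10 calls, the one given above and higher in the IFNγ responses of IRF2KO (2 of 11 rose; adjusted p = 0.016 with an estimated correlation) and DKO (2 of 11; 0.0080).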

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

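The tests of carry-over, of a mislabelled line and of power were chosen after the results they measure were seen, and the other tests before. The genes counted and named in the next 3 paragraphs were called in a test of the difference between a mutant's response and that of WT, given in log2 units with SE, n = 2 per group. The values in the paragraphs after these come from the tests named there.

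In IRF1KO 3 genes responded differently to IFNα: Gm12250 (−3.55 ± 0.30), Tgtp2 (−2.96 ± 0.43) and Ifi47 (−2.04 ± 0.24). Tgtp2 is listed at 0 in the media groups of WT and IRF1KO, so its value depends on the pseudocount. Its call was lost without either replicate of WT media, WT IFNα or IRF1KO media (−3.54 to −2.37). To IFNγ 10 genes differed, with Gm12250 at −3.38 ± 0.30, Iigp1 at −2.94 ± 0.35, Ifi47 at −2.61 ± 0.24, Gbp4 at −2.51 ± 0.39, Tgtp2, with both media groups at 0 again, at −2.45 ± 0.43, and Gbp6, listed at 0 in IRF1KO media, at −2.02 ± 0.30. The call of Gbp4 held only without IRF1KO IFNγ replicate 2 or IRF1KO media replicate 1 (−2.75 to −2.27), and that of Tgtp2 in none of the 8 fits without 1 library (−2.68 to −2.22). Gbp6 lost its call without IRF1KO IFNγ replicate 1, IRF1KO media replicate 2, WT IFNγ replicate 1 or WT media replicate 2 (−2.15 to −1.89).

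In IRF2KO 8 genes differed with IFNα: Rsad2 (4.28 ± 0.31), Cmpk2 (2.73 ± 0.33), Gm14446 (2.62 ± 0.26), Ifit1 (2.53 ± 0.32), I830012O16Rik (2.23 ± 0.31) and Ifit2 (2.15 ± 0.33), with Ifit3 and Trim21 called outside the rule for named genes. Rsad2 and I830012O16Rik are listed at 0 in WT media. I830012O16Rik lost its call without WT IFNα replicate 1 (1.82 to 2.64). Ifit2 lost it without IRF2KO IFNα replicate 1, IRF2KO media replicate 1 or either replicate of WT IFNα or WT media (1.79 to 2.5). To IFNγ 4 genes differed: Rsad2 (2.40 ± 0.31, with WT media at 0), Gbp2 (−4.64 ± 0.57), Gbp3 (−2.62 ± 0.35) and Gbp7 (−1.79 ± 0.23), the last 3 from raised media levels in IRF2KO. Without IRF2KO IFNγ replicate 2 the calls of Gbp3 (−2.77 to −2.47) and Gbp7 (−1.94 to −1.65) were lost.

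In DKO 10 genes differed with IFNα. Rsad2 (2.80 ± 0.31), I830012O16Rik (1.82 ± 0.31) and Mx2 (1.55 ± 0.26), all listed at 0 in WT media, Gm14446 (1.72 ± 0.26), Trim21 (1.60 ± 0.23) and Parp10 (1.58 ± 0.27) responded more. Gm12250 (−3.24 ± 0.30), Iigp1 (−2.12 ± 0.35), Oasl2 (−1.82 ± 0.23) and Ifi47 (−1.57 ± 0.24) responded less. In the 8 fits without 1 library, I830012O16Rik (1.69 to 1.95), Parp10 (1.40 to 1.76) and Mx2 (1.45 to 1.65) were called in none. Gm14446 (1.56 to 1.89) was called only without DKO media replicate 1, Trim21 (1.41 to 1.78) only without DKO IFNα replicate 2 or WT IFNα replicate 2, and Iigp1 (−2.29 to −1.95) and Ifi47 (−1.70 to −1.45) only without DKO IFNα replicate 2. To IFNγ 11 genes differed, with Gbp2 at −5.38 ± 0.57, Iigp1 at −4.11 ± 0.35, Gm12250 at −3.28 ± 0.30, Gbp3 at −2.88 ± 0.35, Tgtp2, listed at 0 in both media groups, at −2.75 ± 0.43, Ifi47 at −2.74 ± 0.24 and Gbp7 at −2.04 ± 0.23. The media levels of Gbp2, Gbp3 and Gbp7 were raised in DKO. Tgtp2 kept its call only without DKO IFNγ replicate 2 or WT IFNγ replicate 2 (−3.07 to −2.44).

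Guanylate-binding protein genes were higher in IRF2KO than in WT in media. Carry-over of IFNγ-treated cells or reads is argued against, since 19 other genes that IFNγ raised at least 8-fold in WT had a median of 0.185 (SE 0.164), against 4.392 for 5 such Gbp genes. A difference of this one set of cultures is argued against by the single libraries, where the 7 called Gbp genes had a median difference of 3.946 at 0 h, with all 7 higher; that median is the value of Gbp5, which is listed at 0 in WT, and lies between Gbp4 (4.52) and Gbp7 (3.10). An effect of the pseudocount is argued against, since all 7 stayed called at a pseudocount of 5. In DKO, the other line with IRF2 targeted, the same 7 genes were called higher than in WT and in IRF1KO (Gbp2 by 5.51 ± 0.41 and 6.56 ± 0.41), but the labels do not say whether DKO and IRF2KO share a clone, so a difference between cell clones other than IRF2 stays open. Reads shared between Gbp genes were not tested.

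The larger IFNα response of 8 genes in IRF2KO was set against the scaling of the libraries, and at least 7 of the 8 stayed called under TMM or quantile scaling. In the single libraries the same 8 genes had a median difference of the responses of 1.82, above 0 in 8 of 8. At this pseudocount of 1 that argues against a difference of this one set of cultures. With 1 library per group, a stronger response of a single culture in that series is not excluded. The check shares the pseudocount, so it cannot show whether low WT values set the size. Ifit3 there stood at 58.9 TPM with IFNα against 0.41 at 0 h in WT, and at 362 against 1.99 in IRF2KO. At a pseudocount of 0.1 none of the 8 was called, with Rsad2 at 2.40 ± 0.74 instead of 4.28 ± 0.31, Cmpk2 at 0.77 ± 0.77 instead of 2.73 ± 0.33 and Ifit2 at 2.22 ± 0.35 instead of 2.15 ± 0.33. Trim21 had 2.18 ± 0.36 instead of 1.36 ± 0.23. The fold of 6 of the 8 genes fell, that of Ifit2 and Trim21 rose, and the SE grew for all 8, so low WT values may set part of the size of some, and this stays open. Trim21 was called only without WT IFNα replicate 2 among the fits without 1 library (1.18 to 1.55). An IRF2 effect and a clonal difference stay open as well.

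No gene was called between IRF1KO and WT in media. WT cells under the IRF1KO label are argued against, since 12 genes lower in DKO than in IRF2KO had a median of −0.253 (SE 0.108) in IRF1KO minus WT, below 0 in 10 of 12, and were lower as a set with their estimated correlation of 0.334 (p = 0.024; 0.044 by fry). That spread is the one between libraries of a group, which the labels do not call separate cultures. Too little power stays open, since the half-width of the 95% interval of the median gene, 0.407, is not adjusted for the 11842 genes tested, and to be the only gene called the median gene would need a log2 change of 1.32. Changes such as that of Psmb9 (−0.76 ± 0.22, adjusted p = 1) may be missed. The 67.2% of 2-fold changes recovered in simulated data came from IRF2KO against WT with 200 changed genes. That rate does not give the power of this comparison, where no gene was called. Residual IRF1 protein was not measured and stays open as well.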

How the results depend on the processing

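All alternatives were chosen before the results were seen. Of 545 results of single named genes, none changed direction in 7708 refits, but many of these refits could not turn a sign. The block, robust variances, the compared groups alone, the filters and the fold of at least 2 leave the fold change itself as it was. In a comparison of 2 groups, genes named because their libraries did not overlap cannot turn without 1 library either. Calls were lost for 57 at a pseudocount of 0.1, 23 at 5, 37 without the filter on low values, 4 of 471 with a mean of at least 5 TPM, 9 under TMM and 14 under quantile scaling, 7 with robust variances, 80 when a fold of at least 2 was required and 338 in fits of the compared groups alone, which have few libraries to estimate the spread. In fits without 1 library, where the lone library of a group is assumed to vary like the others, 550 of 2332 were lost. The replicate block gained a call for 2 named genes (Cd274 with IFNα in WT and Psmb9 in IRF2KO media) and changed no other call of a named gene. Of the 380 list tests it ended 2 camera calls (sensing genes in DKO media and the IRF family in the IFNγ interaction of IRF2KO) and gained 16, among them checkpoint ligands with IFNα in WT and cytokines and chemokines for IFNγ against IFNα, and of the 114 tests of mutant against WT under interferon it ended 3 and gained 9. Counts of called genes follow as totals, with the main totals given first for each comparison: WT IFNα 123, WT IFNγ 149, WT IFNγ against IFNα 91, IRF2KO media 99, DKO media 90, DKO against IRF2KO 14, DKO against IRF1KO 79, IRF1KO IFNα 97, IRF1KO IFNγ 137, IRF2KO IFNα 165, IRF2KO IFNγ 134, DKO IFNα 120, DKO IFNγ 92, and for the interactions IRF1KO with IFNα 3 and IFNγ 10, IRF2KO 8 and 4, DKO 10 and 11.

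With the replicate number as a block the totals were 229 for WT IFNγ, 177 for IFNγ against IFNα, 213 for IRF2KO and 190 for DKO in media, 23 for DKO against IRF2KO, 201 for DKO against IRF1KO, 209, 243 and 196 for the IFNγ responses of IRF1KO, IRF2KO and DKO, and 7 and 17 for the IFNγ interactions of IRF2KO and DKO. With the compared groups alone they were 56 for WT IFNα, 46 for WT IFNγ, 20 for IFNγ against IFNα, 4 for IRF2KO and 20 for DKO in media, 0 for DKO against IRF2KO (limma, with 995 at an unadjusted p under 0.05 in the fit to all groups), 14 for DKO against IRF1KO, 34, 68 and 38 for the IFNα responses and 13, 63 and 9 for the IFNγ responses of IRF1KO, IRF2KO and DKO, 1 and 3 for the IFNγ interactions of IRF1KO and DKO, and 1 and 4 for the IFNα interactions of IRF2KO and DKO. A fold of at least 2 left 58 for IRF2KO and 59 for DKO in media and 51 for DKO against IRF1KO. A mean of at least 5 TPM left 65 for IRF2KO in media, 52 for DKO against IRF1KO, and 6 each for the interactions of IRF1KO with IFNγ and DKO with IFNα. Without the filter there were 3 for IRF1KO in media, 7, 14 and 16 for the IFNα interactions of IRF1KO, IRF2KO and DKO, and 17 for DKO with IFNγ. A pseudocount of 0.1 gave 22 for DKO against IRF2KO and 2, 0, 1 and 7 for the interactions of IRF1KO with IFNγ, IRF2KO with IFNα, DKO with IFNα and DKO with IFNγ (the 0 from limma, with 394 at an unadjusted p under 0.05 at a pseudocount of 1). A pseudocount of 5 gave 8 for DKO against IRF2KO, 5, 15 and 16 for the IFNα interactions of IRF1KO, IRF2KO and DKO, and 7 for IRF2KO with IFNγ. TMM scaling gave 2 higher and 3 lower for IRF2KO with IFNγ, against 1 and 3, and no other total moved by over 1.5 times under TMM, quantile scaling or robust variances.

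Without 1 library the totals ranged from 87 to 104 for WT IFNα, 93 to 124 for WT IFNγ, 72 to 76 for IFNγ against IFNα, 0 to 2 for IRF1KO, 40 to 57 for IRF2KO and 42 to 54 for DKO in media, 7 to 11 for DKO against IRF2KO, 38 to 52 for DKO against IRF1KO, 73 to 90 and 64 to 109 for IFNα and IFNγ in IRF1KO, 108 to 160 and 67 to 103 in IRF2KO, and 84 to 96 and 51 to 87 in DKO. For the interactions with IFNα and IFNγ they ranged from 2 to 3 and 4 to 8 in IRF1KO, 4 to 9 and 2 to 5 in IRF2KO, and 3 to 10 and 8 to 13 in DKO. The median signed difference of the called genes in the single libraries was 0.696, and 0.921 at a pseudocount of 0.1, 0.428 at 5 and 0.466 with the block. At a pseudocount of 5 the difference of the responses in the single libraries, IRF2KO minus WT, turned sign for the ISGF3-type genes with LPS (−0.001) and for the GTPases with IFNα (0.268). No paired analysis was possible for the single libraries because they have 1 library per group.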

Other observations

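The comparison of single libraries with random lists was planned before the results were seen, and naming their largest differences followed a fixed rule. Il6 and the counterparts of the named genes in the other line were looked up after the values were seen. The single libraries include none kept for 2 h without treatment. Each difference from 0 h, with LPS or with IFNα, therefore also holds any effect of 2 h in culture. After 2 h of LPS, a bacterial trigger of TLR4, WT cells had 228 genes at least 2-fold higher and 93 lower than at 0 h, n = 1 each. The interleukin genes Il1b and Il1a stood at 809 and 1079 TPM against 3.19 and 8.91 at 0 h, and the chemokine genes Cxcl2 and Cxcl10 at 257 and 989 TPM against 0.99 and 15.2. Fos, an immediate early gene, was lower on the log2 scale (−3.09), as were Dusp6, a phosphatase of ERK kinases (−2.93), and Rgs2 (−2.73). Of the cytokines and chemokines 17 of 25 were at least 2-fold higher (median 2.62), and of the NF-kB feedback and LPS early genes 17 of 20 (median 1.48).

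In IRF2KO with LPS 250 genes were at least 2-fold higher and 196 lower. Cxcl2 stood at 285 TPM against 0.17, Il1b at 1039 against 3.50 and Cxcl10 at 2347 against 13.9, and Il6 at 293 against 0.70, where WT had 91.9 against 0.79. The cytokine list had a median of 3.24, and its response was larger than in WT by a median of 0.505, above the central 95% of random lists (−0.160 to 0.034), with 7 genes at least 2-fold apart. A larger response was not always a higher level with LPS. Cxcl3 stood at 170 TPM in IRF2KO, listed at 0 at 0 h, and at 235 TPM in WT, from 3.40. Il6 and Cxcl10 were higher with LPS in IRF2KO than in WT. Stress and immediate early genes moved with the cytokine list, with a response larger than in WT by a median of 0.297 (random lists −0.208 to 0.050) and a 0 h difference of −0.161 (−0.087 to 0.130). The antiviral genes Rsad2 and Ifit1 reached 17.4 and 42.7 TPM in IRF2KO with LPS and 0.51 and 2.97 in WT. At 0 h Ifit1 stood at 5.64 TPM in IRF2KO and 1.71 in WT. Over the ISGF3-type list the difference of the LPS responses had a median of 0.052 (random lists −0.215 to −0.026). There 3 of 42 genes had a response at least 2-fold larger in IRF2KO, and 0 a smaller one. Cell cycle genes had a median of −0.299 in the LPS response of IRF2KO, while the median of all genes was −0.148. The NF-kB list had 16 of 20 genes at least 2-fold higher there (median 1.60). The LPS response in IRF2KO minus that in WT had a median of −0.198 for cell cycle genes (random lists −0.158 to 0.024). For the NF-kB list it was 0.073 (−0.238 to 0.022). Of 18 lists 4 lay above the random lists in that difference and 1 below.

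With IFNα, the single WT library had 167 genes at least 2-fold higher and 23 lower, and IRF2KO 188 and 26. Ifit3 was higher by 5.41 in WT and 6.92 in IRF2KO than at 0 h, and Ifit1 by 4.80 and 6.62. The ISGF3-type genes had medians of 2.13 and 2.52, and a median difference of the responses of 0.456, above the central 95% of random lists (−0.125 to 0.056). Stress and immediate early genes moved the same way, with a median difference of 0.158 (random lists −0.141 to 0.097) and −0.134 in the WT response (−0.070 to 0.112), as did MHC class I presentation with 0.146 (−0.117 to 0.081). At 0 h the MHC class II genes had a median difference between IRF2KO and WT of 0.599, outside −0.101 to 0.129 for random lists, while the replicated libraries gave no camera call for that list. At 0 h Arg1, which encodes arginase, stood at 1.75 TPM in IRF2KO and 18.2 in WT, and Cd274 at 30.7 and 13.4. Neither gene was called between IRF2KO and WT in the replicated media libraries. At 0 h in the single libraries other lists differed too. The interferon-inducible GTPases had a median difference of 1.42 in the single libraries at 0 h, with 9 of 16 at least 2-fold higher, and MHC class I presentation one of −0.020. Of 18 lists quantified 8 lay above the random lists at 0 h and 1 below. Among the 8 were the ISGF3-type genes (0.218, random lists −0.046 to 0.116; 5 at least 2-fold higher and 3 lower), sensing genes (0.246, −0.065 to 0.127; 0 and 2) and dendritic cell markers (0.195, −0.132 to 0.176). In the replicated media libraries these 3 lists had medians of −0.171, −0.113 and −0.249. No replicate exists for these libraries, so none of these differences was tested.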
